A study of Mus musculus with 6 samples.

How the data were processed

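Lungs of balb/c mice at D0 and D14 after implantation of K7M2 osteosarcoma cells were sequenced as 3 libraries per day. Per the labels' protocols, total RNA was isolated with TRIzol and chloroform and libraries were made with an NEB RNA kit. The extraction text names bone marrow-derived macrophages, while the tissue label and the titles give lungs; the samples are taken as lungs. Strand handling, the counting tool and the annotation release are not given in the sources used here. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.1.0, StringTie 1.3.4b and edgeR were used with the genome build GRCm38, with no role or order stated.

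The deposited table holds estimated counts per gene symbol, not scaled for depth, with 1 column per library and 0 columns beyond the 6 samples. They are treated as estimated and rounded because StringTie derives counts from coverage; the values used were whole before rounding. Of 29757 lines, 4 were left out. 2 lines, for Tnf and Tgfb1, were empty, and 2 displaced lines after them held values that are not whole, so these genes are not analysed here. Another 50 lines repeated a symbol. The line with the highest total kept the symbol and the others were kept apart, and summing them was an alternative chosen after seeing the data. Library totals ran from 14878101 to 17385006. In a library without a count of a gene, 3 counts set the limit.

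Gene tests used edgeR 4.0.16 in R 4.3.3 with TMM factors, the default low count filter, and the robust quasi-likelihood F test, two-sided, on all 6 libraries with no covariate. P-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were scaled by TMM, and log2 CPM used a prior count of 2. A total of 48 gene lists was written before the data were examined, and 47 had at least 3 tested members. They were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists), again with an estimated correlation, and with fry. "Adjusted over the list alone" means the adjustment of gene p-values within one list, with no further adjustment over the lists. With 3 libraries per group, a permutation test of one gene could reach no p below 0.1, so none was used for the comparison.

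The genes named were fixed by rule before the data were examined: up to 12 genes past the threshold per direction with a mean of at least 1 CPM, ranges that do not overlap and an established symbol, filled to 5 by smallest p; for each list, its members past the threshold or else its 2 most abundant members; and a panel of niche genes. Some genes that this rule or a list test selects are not reported here. Positions and biotypes come from GENCODE for GRCm38, in which 98.1% of the tested symbols were found. Genes that overlap the leading genes were looked up there. Those of Spry4, Irs2, Dusp8, Zfx and Ltb had at most 5 counts in a library.

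Alternatives tried were DESeq2 1.42.0, limma-voom, RLE factors, no scaling factors, no low count filter, a filter of at least 1 CPM in 3 libraries, a fit without robust estimation, the replicate number as a block, each library left out in turn, and an added limit on the absolute log2 fold change of 1. The gene test was tested on simulated data, 3 simulations with 17374 genes and 200 changed genes each, drawn from the real means and library sizes. At an adjusted p of 0.05 it recovered 20.3% of the genes changed by a log2 fold change of 1 and 81% of those changed by 2, with 28 false calls among 332. Transcript lengths were those of the longest annotated transcript. The trend of log2 CPM on length was fitted per library by lowess with a span of 0.3 on 16567 genes outside the lists.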

Results

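Lungs of balb/c mice were profiled by bulk RNA sequencing on day 0 (D0) and day 14 (D14) after orthotopic implantation of K7M2 cells, a mouse osteosarcoma line that spreads to the lung. Each day had 3 libraries, numbered as biological replicates, and the design text speaks of 3 independent experiments. The D0 libraries held 16001097, 15111727 and 14878101 counts, and the D14 libraries 17385006, 16190362 and 16171595. After the filter on low counts, 17686 genes were tested. Where a gene had no count in a library, 3 counts in that library would correspond to between 0.173 and 0.202 CPM, counts scaled to library size, a limit that covers counting error only. The labels do not say whether each library came from 1 mouse, so p-values measure the spread between these libraries.

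The libraries of one day were not much closer to each other than to those of the other day. Pearson correlations of log2 CPM were 0.931 to 0.969 among the D0 libraries, 0.968 to 0.970 among the D14 libraries and 0.919 to 0.970 between days. D0 replicate 3 stood apart on the first principal component, which held 42.6% of the variance, at 82.85 against −41.48 to 15.71 in the other libraries. In that library the haemoglobin genes took 4.99% of the counts and the 10 most abundant genes 12.6%, against 0.985% to 2.77% and 5.89% to 9.03% elsewhere. No pair of libraries agreed within sampling noise.

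The comparison of D14 with D0 asks how the lung changes in the period named in the series title as the formation of a pre-metastatic niche. The series holds no D14 group without implanted cells. Effects of the tumour, the procedure, the animals' age and the day of collection therefore cannot be told apart for any gene or list. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 48.6 ± 8.35 CPM at D0 to 194 ± 10.7 CPM at D14 (SD, n = 3 each), a log2 fold change of 2.00 (SE 0.17; adjusted p = 0.0224, edgeR quasi-likelihood test). Irs2, an adaptor protein of the insulin and IGF receptors, rose from 46.9 ± 4.41 to 140 ± 11.7 CPM, a log2 fold change of 1.58 (SE 0.15; adjusted p = 0.0265). Zfx, an X-linked zinc finger transcription factor, fell from 58.4 ± 6.39 to 8.93 ± 1.85 CPM, a log2 fold change of −2.71 (SE 0.20; adjusted p = 0.0224). Crk, an adaptor protein that links tyrosine kinases to cytoskeletal signalling, fell from 163 ± 16.9 to 58.1 ± 2.77 CPM, a log2 fold change of −1.49 (SE 0.14; adjusted p = 0.0290). In GRCm38 coordinates these protein-coding genes lie on chromosome 18 from 38586247 to 38601415 (Spry4), chromosome 8 from 10984681 to 11008458 (Irs2), chromosome X from 94074631 to 94123702 (Zfx) and chromosome 11 from 75679259 to 75706908 (Crk).

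In all, 6 genes passed an adjusted p of 0.05, 3 higher and 3 lower at D14, and the remaining pair is uncertain because each shares its locus with another annotated gene. One of 2 rows named Ptp4a1, a protein tyrosine phosphatase, was higher at D14, with 631, 518 and 528 counts against 53, 70 and 25 at D0 (log2 fold change 3.47, SE 0.32; adjusted p = 0.0265). The other row of that name had 427, 590 and 677 counts at D14 and 963, 597 and 1166 at D0, and the sum of both rows differed by a log2 fold change of 0.17 (SE 0.25; adjusted p = 0.765). Mir1199, on chromosome 8 from 84011515 to 84011633, lies on the same strand within the annotated gene 2210011C24Rik. It had 45, 77 and 57 counts at D0 and 1 count in each D14 library, a ratio of D0 to D14 of 61.5 with a 95% exact interval for counting error of 20.7 to 301 (adjusted p = 0.0224). A row named Misp3, a later symbol of that gene, had 552, 658 and 739 counts at D0 and 464, 293 and 214 at D14.

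The named genes that came closest without passing were Dusp8, a phosphatase of MAP kinases, and Tnfrsf10b, a death receptor for TRAIL, on the higher side. Their log2 fold changes were 1.35 (SE 0.16) and 1.62 (SE 0.19), each with an adjusted p of 0.0786. On the lower side were Ltb, lymphotoxin beta, at −1.39 (SE 0.19; adjusted p = 0.0857) and Fzd2, a Wnt receptor, at −1.01 (SE 0.16; adjusted p = 0.167). At an unadjusted p under 0.05 stood 2223 genes, 969 higher and 1254 lower. D0 and D14 ranges did not overlap in 21.6% of the tested genes, where splits of the libraries give 10% on average. Genes vary together over these libraries, so 1 split can lie far from that average without an effect of the day. The share was not computed for the other splits. The number of calls depended on the libraries: it was 0 without any one of the D14 libraries, 3 without D0 replicate 1, 1 without D0 replicate 2 and 22 without D0 replicate 3. DESeq2 on the same counts called 274 genes, and edgeR with no filter on low counts called 26.

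**Figure D1:**
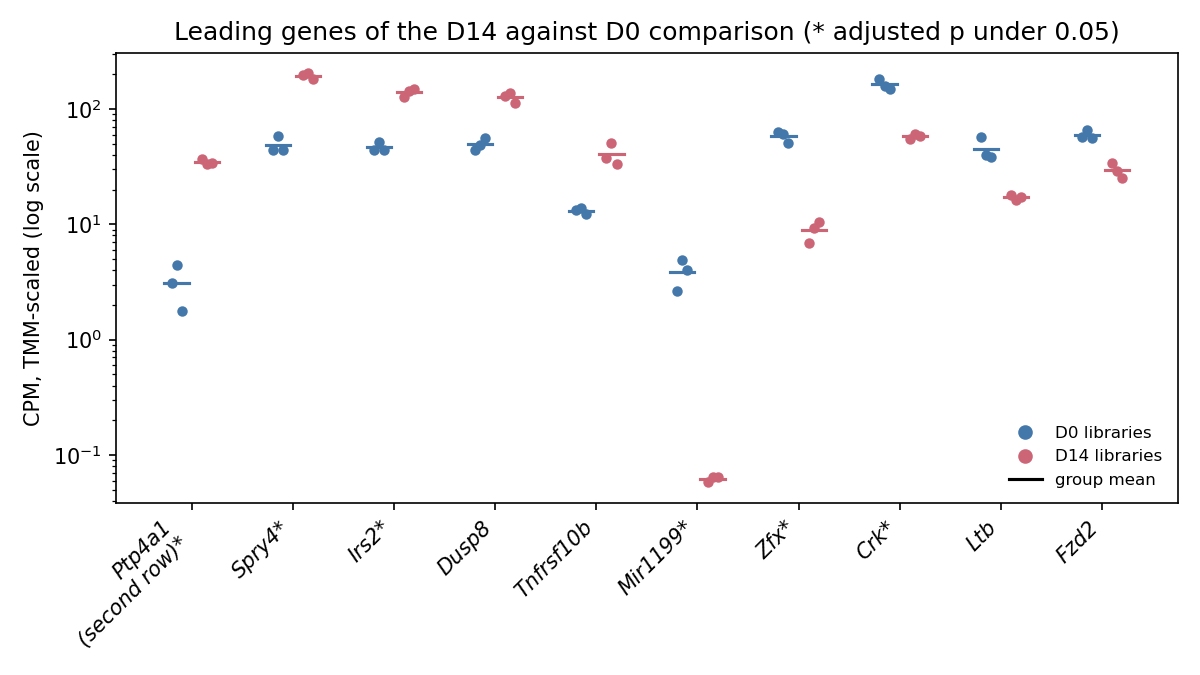
CPM on a log axis of the 10 genes named by the fixed rule, with 1 point per library, D0 in blue and D14 in red, and a line at each group mean (n = 3). Genes with an asterisk passed an adjusted p of 0.05. Spry4 averaged 48.6 CPM at D0 and 194 CPM at D14. That the D0 and D14 points of a gene do not overlap was a condition of the rule.

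Of 47 gene lists tested as groups, 18 passed with the preset correlation of camera, 13 higher and 5 lower at D14. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.401, and with fry 0 passed. Other splits of the 6 libraries into 3 and 3 gave up to 24 lists with the preset correlation. By fry's test for change in either direction, 5 lists passed: immediate early response (adjusted p = 0.0439), heat shock response (0.00697), the pre-metastatic niche panel (0.0439), matrix remodelling enzymes (0.00957) and classical macrophage activation (0.00957). That test asks whether members change at all, not whether they change more than other genes. It was not run on other splits or with a library left out. No list had a member past the threshold over all genes, and members are counted below as adjusted over the list alone. Genes named on that ground, outside the 2 most abundant members of a list, were chosen after their values were seen.

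Immediate early genes, transcription factors and regulators that stimuli induce within minutes, were higher at D14 in 19 of 20 measured members, with a median log2 fold change of 0.67 (camera adjusted p = 3.01e-08, and adjusted p = 0.674 with an estimated correlation). Adjusted over the list alone, 10 members rose, 1 fell and 9 did not pass. The median was 0.418 without D0 replicate 1 and 1.01 without D0 replicate 2. Nr4a2 rose from 8.49 ± 2.64 to 30.2 ± 4.40 CPM, Nr4a1 from 97.3 ± 56.9 to 400 ± 30.9 CPM and Fos from 50.5 ± 18.3 to 114 ± 5.42 CPM. Ier3 fell from 172 ± 12.8 to 79.7 ± 18.6 CPM (SD, n = 3). The most abundant members, Jund and Dusp1, had log2 fold changes of 0.11 (SE 0.22) and 0.67 (SE 0.41) and did not pass. Heat shock genes were higher in 12 of 12 members, with a median of 0.47 (adjusted p = 9.02e-07, and adjusted p = 0.401 with an estimated correlation), and 6 rose adjusted over the list alone. Hsph1, a chaperone of the HSP110 family, rose from 44.7 ± 7.71 to 94.9 ± 13.3 CPM and Hspa1a, an inducible HSP70, from 10.5 ± 3.59 to 40.0 ± 24.6 CPM. Without D0 replicate 1, D0 replicate 2, D14 replicate 1 or D14 replicate 2, the count of heat shock genes was 2, 3, 1 and 1, and with no scaling factors it was 3. The abundant chaperones Hspa5 and Hspa8 had log2 fold changes of 0.44 (SE 0.20) and 0.48 (SE 0.22).

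Glucocorticoid response genes were higher in 14 of 14 members, with a median log2 fold change of 0.96 (adjusted p = 1.81e-06, and adjusted p = 0.674 with an estimated correlation). Of these only Klf9, a transcription factor, rose adjusted over the list alone, from 164 ± 44.6 to 336 ± 66.9 CPM. Without 1 library this count was 0 (D14 replicate 2 or 3) to 5 (D0 replicate 3), with 4 without D0 replicate 1 and 3 without D14 replicate 1, and it was 5 with DESeq2, 3 with no scaling factors and 2 with no low count filter. The list's median was 0.68 without D0 replicate 1, which had its lowest mean log2 CPM, 5.225. The other D0 libraries had 6.49 and 6.71, and the D14 libraries 6.95 to 7.52. Errfi1, a feedback inhibitor of the EGF receptor, had 316 ± 188 CPM at D0 and 968 ± 43.7 CPM at D14, and Dusp1 400 ± 211 and 636 ± 73.9 CPM. The circadian clock list did not pass (median −0.01, mean −0.09, with the test's direction upward; adjusted p = 0.531), though Bhlhe40 rose and Bhlhe41 fell adjusted over the list alone. Its most abundant members were Per1 at 1.25 (SE 0.66) and Tef at −0.14 (SE 0.58). Clock genes varied widely within D0: Dbp had 14.2, 166 and 71.2 CPM in the D0 libraries and 28.6, 8.29 and 9.17 CPM in the D14 libraries.

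Endothelial genes were higher at D14 in 17 of 19 members, with a median log2 fold change of 0.61 (adjusted p = 4.47e-06, and adjusted p = 0.674 with an estimated correlation). Adjusted over the list alone, Cldn5, a tight junction protein, rose from 665 ± 64.6 to 1086 ± 148 CPM and Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, from 90.5 ± 39.6 to 294 ± 33.4 CPM. Cdh5, VE-cadherin, had 700 ± 355 and 1099 ± 84.4 CPM and did not pass. Of the endothelial list 11 members passed without D0 replicate 1, 1 without D0 replicate 2 and 0 without D14 replicate 1 or D14 replicate 2. The median was 0.916 without D0 replicate 1 and 0.343 without D0 replicate 3. D0 replicate 3 had the lowest mean log2 CPM of this list, 6.81, against 7.87 and 7.38 in the other D0 libraries and 7.96 to 8.0 at D14.

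The pre-metastatic niche panel, genes tied by earlier work on other tumours to lung niches, was higher in 20 of 24 members, with a median of 0.36 (adjusted p = 0.000707, and adjusted p = 0.674 with an estimated correlation). S1pr1, a sphingosine-1-phosphate receptor of endothelium and lymphocytes, was the 1 member that rose adjusted over the list alone, from 248 ± 36.0 to 686 ± 67.0 CPM (adjusted p = 0.0786 over all genes), and the count was 4 without D0 replicate 1, 5 without D14 replicate 1, 2 with no low count filter and 8 with DESeq2, 7 higher and 1 lower. Matrix remodelling enzymes were higher in 18 of 22 members, with a median of 0.36 (adjusted p = 0.00152, and adjusted p = 0.674 with an estimated correlation). This list shares Mmp2, Mmp9, Timp1, Lox, Loxl2 and Loxl4 with the niche panel, so the shifts of both are not independent. Adjusted over the list alone, 3 members rose and 1 fell. Adamts1, a secreted metalloproteinase, rose from 125 ± 34.0 to 419 ± 60.2 CPM and Lox, a collagen crosslinking enzyme, from 68.8 ± 17.04 to 153 ± 60.0 CPM, while Mmp11 fell from 66.9 ± 5.85 to 38.7 ± 6.45 CPM. The count of 4 became 2 without D0 replicate 2 or D14 replicate 3 and 1 without D14 replicate 2, where the median was 0.213. Timp3 and Timp2, tissue inhibitors of metalloproteinases, had log2 fold changes of 0.54 (SE 0.19) and 0.04 (SE 0.16), the latter negative without scaling factors. The fibrillar collagen and matrix list did not pass (median 0.02, adjusted p = 0.129) except without D0 replicate 3 (median 0.0618, adjusted p = 0.0327) or D14 replicate 1 (median 0.064, adjusted p = 0.0374), with Sparc at −0.02 (SE 0.16) and Col3a1 at −0.13 (SE 0.19).

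The panel genes fixed for this comparison gave no call over all genes. S100a8 and S100a9, calprotectin subunits of neutrophils and monocytes, had 35.0 ± 6.28 and 61.8 ± 14.7 CPM at D0 and 37.0 ± 20.3 and 63.9 ± 31.4 CPM at D14. Their log2 fold changes were 0.08 (SE 0.38) and 0.05 (SE 0.36). Mmp9 had a log2 fold change of 0.35 (SE 0.38), Fn1, fibronectin, 0.70 (SE 0.25) and Vegfa −0.28 (SE 0.18). Saa3 stood at −1.81 (SE 0.99), with 50.3 CPM in D0 replicate 3 and 2.27 to 7.60 CPM in the other libraries. Arg1 stood at −1.22 (SE 0.47), Spp1 at −0.46 (SE 0.33) and Cd274, the checkpoint ligand PD-L1, at −0.04 (SE 0.20). The chemokines Ccl2, Cxcl1 and Cxcl2 stood at 0.18 (SE 0.89), −0.31 (SE 0.75) and −0.27 (SE 0.67). Il6 was below the count filter, with 0 to 23 counts per library.

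B cell genes were lower at D14 in 15 of 15 members, with a median log2 fold change of −0.78 (adjusted p = 1.61e-06, and adjusted p = 0.674 with an estimated correlation), and 7 fell adjusted over the list alone. Cd79a and Cd79b, the signalling chains of the B cell receptor, fell from 44.4 ± 14.4 to 21.7 ± 1.15 and from 51.7 ± 14.5 to 27.2 ± 4.47 CPM. Ighm, the most abundant member, had a log2 fold change of −0.36 (SE 0.64) and did not pass. This count was 1 without D0 replicate 1, D0 replicate 3 or D14 replicate 3, 0 without D14 replicate 1 or D14 replicate 2, and 11 without D0 replicate 2. The plasma cell list did not pass (median −0.31, adjusted p = 0.857; Sdc1 −0.26, SE 0.20, and Igkc −0.48, SE 0.62). MHC class II genes were lower in 10 of 10 members without passing (median −0.29, adjusted p = 0.0526), but passed with 6 other settings (adjusted p = 0.015 without D14 replicate 1), with Cd74 at −0.07 (SE 0.25) and H2-Aa at −0.06 (SE 0.24). H2-Ob, an MHC class II gene of B cells, fell adjusted over the list alone, from 16.9 ± 4.21 to 7.45 ± 1.8 CPM.

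Dendritic cell genes were higher in 9 of 12 members (median 0.28, adjusted p = 0.0195, and adjusted p = 0.674 with an estimated correlation), and 0 passed adjusted over the list alone, Fscn1 standing at 0.65 (SE 0.32) and Zbtb46 at 0.39 (SE 0.31). The neutrophil list did not pass, with 14 of 20 members positive, a median of 0.22 and an adjusted p of 0.203, though it passed without D14 replicate 3 (median 0.436, adjusted p = 0.00855). Hp, also in the club and acute phase lists, stood at 0.16 (SE 0.24). Lcn2 stood at −1.45 (SE 0.73), with 446 CPM in D0 replicate 3 and 60.4 to 74.5 CPM elsewhere. Nor did the granulocyte precursor list (median −0.55, adjusted p = 0.791; Gfi1 −0.55, SE 0.51, and Prtn3 −0.66, SE 0.47) or the classical monocyte list (median −0.25, adjusted p = 0.926; Mgst1 −0.25, SE 0.23). In the main fit no macrophage list passed camera. The alveolar macrophage list had a median of −0.44 (adjusted p = 0.124, and 0.0013 without D0 replicate 1). Ccl6 stood at −0.78 (SE 0.55), with 633 CPM in D0 replicate 3 and 124 to 204 CPM elsewhere. Car4, also in the endothelial list, stood at 0.22 (SE 0.15). The interstitial macrophage list had a median of −0.30 and a mean of −0.10, with the test's direction upward (adjusted p = 0.832; Apoe 0.06, SE 0.47), and Lyve1 was its 1 call over the list alone. Without D0 replicate 3 it passed upward (median 0.259, adjusted p = 0.0013), as did alternative activation genes (median 0.269, adjusted p = 0.0434). Alternative activation genes had a median of −0.03 (adjusted p = 0.908) with all libraries. Chil3 stood at −1.19 (SE 0.66), with 427 CPM in D0 replicate 3 and 58.4 to 115 CPM elsewhere, and Mrc1 at 0.10 (SE 0.21). Classical activation genes had a median of 0.25 (adjusted p = 0.0939; Ptgs2 0.75, SE 0.38, and Ccl5 −0.01, SE 0.23), and Il1a rose adjusted over the list alone, from 11 ± 1.76 to 24.9 ± 1.20 CPM. The classical activation list passed without D0 replicate 3 (median 0.516, adjusted p = 0.00919) or D14 replicate 3 (median 0.476, adjusted p = 0.00186) and with 3 other settings.

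T cell genes (median −0.07, adjusted p = 0.857), cytotoxic lymphocyte genes (median −0.11, adjusted p = 0.861) and thymocyte genes (median 0.08, mean −0.01 with the test's direction downward, adjusted p = 0.952) did not pass. Their most abundant members were Tcf7 at 0.12 (SE 0.37) and Trbc2 at −0.53 (SE 0.20), Gzma at −0.13 (SE 0.32) and Il2rb at 0.24 (SE 0.35), and Cd1d1 at −0.32 (SE 0.25). Neither did mast cell genes (median −0.57, adjusted p = 0.474; Cpa3 −0.57, SE 0.44, and Cma1 −0.35, SE 0.47) or immune checkpoint genes (median −0.04, adjusted p = 0.785; Havcr2 −0.24, SE 0.29). Interferon responses did not pass either. The type I list had a median of 0.20 (adjusted p = 0.0613; Bst2 −0.07, SE 0.21) and the interferon gamma list a median of 0.08 (adjusted p = 0.840; Gbp4 0.32, SE 0.38, and Gbp7 0.49, SE 0.34). Chemoattractants had a median of −0.29 (adjusted p = 0.514; Cxcl15 −0.15, SE 0.23, and Csf1 −0.49, SE 0.18) and acute phase and complement genes a median of −0.20 (adjusted p = 0.618; C3 −0.02, SE 0.35).

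Among epithelial lists, club and secretory airway genes were higher in 10 of 12 members (median 0.37, adjusted p = 0.0224, and adjusted p = 0.674 with an estimated correlation). Muc5b, a secreted mucin, rose adjusted over the list alone, from 28.0 ± 4.14 to 51.2 ± 9.85 CPM, and Scgb1a1 and Cyp2f2 stood at 0.62 (SE 0.35) and 0.36 (SE 0.23). This list's call was lost without D0 replicate 2 (adjusted p = 0.310) and without D14 replicate 3 (adjusted p = 0.135). Alveolar type 1 genes (median −0.27, adjusted p = 0.251; Emp2 −0.04, SE 0.20, and Ager −0.29, SE 0.28), alveolar type 2 genes (median −0.17, adjusted p = 0.474; Sftpc −0.46, SE 0.39, and Sftpa1 −0.17, SE 0.26) and ciliated cell genes (median 0.16, adjusted p = 0.111; Tppp3 0.01, SE 0.17, and Foxj1 0.32, SE 0.28) did not pass. Fibroblast genes had a median of 0.02 (adjusted p = 0.531; Inmt −0.42, SE 0.28, and Npnt 0.51, SE 0.29). Osteoblast lineage genes, the cell type of the implanted tumour, had 7 measured members, a median of 0.04 and an adjusted p of 0.501, with Alpl at 0.34 (SE 0.21) and Runx2 at 0.14 (SE 0.19).

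Erythroid genes were higher in 12 of 15 members (median 0.20, adjusted p = 0.00194, and adjusted p = 0.674 with an estimated correlation), and 3 members rose adjusted over the list alone, among them Epb42, a membrane protein gene of red cells. The haemoglobin genes Hba-a1 and Hbb-bt stood at 0.0049 (SE 0.63) and −0.54 (SE 0.53). The erythroid count over the list alone was 0 without D0 replicate 1, D0 replicate 2, D14 replicate 2 or D14 replicate 3. The erythroid median was 0.133 without D0 replicate 2, 0.877 without D0 replicate 3, 0.527 without D14 replicate 1 and 0.545 with limma-voom. Megakaryocyte and platelet genes were higher in 12 of 14 members (median 0.38, adjusted p = 0.0241, and adjusted p = 0.674 with an estimated correlation), with 0 calls over the list alone, Itgb3 at 0.38 (SE 0.17) and Nrgn at 0.01 (SE 0.31). Without D0 replicate 1 the erythroid call was lost (adjusted p = 0.0595), and the megakaryocyte call without D0 replicate 2, D0 replicate 3 or D14 replicate 3 (adjusted p = 0.159, 0.128 and 0.0603). Proliferation genes were higher in 23 of 27 members (median 0.38, adjusted p = 0.000699, and adjusted p = 0.674 with an estimated correlation), with 0 calls over the list alone. Mki67 stood at 0.73 (SE 0.33) and Pcna at −0.02 (SE 0.19), and without D14 replicate 2 the list did not pass (adjusted p = 0.12).

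Skeletal muscle genes were lower at D14 in 14 of 15 members, with a median log2 fold change of −2.03 (adjusted p = 1.86e-06, and adjusted p = 0.674 with an estimated correlation), and 0 fell adjusted over the list alone, against 13 without D14 replicate 2. Their level differed between libraries of one day: Acta1, skeletal actin, had 42.2, 72.5 and 327 CPM at D0 and 1.51, 70.0 and 5.19 CPM at D14, and Ckm, muscle creatine kinase, 32.5, 78.8 and 302 CPM and 21.6, 53.9 and 25.7 CPM. The list's median was −0.72 without D0 replicate 3, −2.49 without D0 replicate 1, −5.32 without D14 replicate 2 and −3.31 with limma-voom. The difference of its mean log2 CPM was −2.75 with all libraries and −2.0 without D0 replicate 3. Genes of stratified squamous epithelium, listed after the data were examined, varied over the same libraries. Krt13 had 12.7, 198 and 798 CPM at D0 and 0.290, 56.2 and 0.192 CPM at D14. Cardiac muscle genes were higher in 10 of 14 members (median 0.68, adjusted p = 0.000729, and adjusted p = 0.674 with an estimated correlation). Adjusted over the list alone Myh6, the cardiac alpha myosin, rose from 47.5 ± 7.26 to 140 ± 60.7 CPM, with Nppa and Ryr2, while Myh7 stood at −0.06 (SE 0.15); without D0 replicate 1 the list did not pass (median 0.376, adjusted p = 0.108), and without D0 replicate 2 or D0 replicate 3 no member did over the list alone. Adipose genes had a median of 0.55 (adjusted p = 0.791; Car3 0.87, SE 1.39, and Lpl 0.16, SE 0.54). They passed upward without D14 replicate 1 (median 1.01, adjusted p = 0.0241) and downward without D14 replicate 3 (median −1.41, adjusted p = 0.00386), and their mean log2 CPM was 6.78 in D14 replicate 3 against 2.68 to 5.20 in the other libraries.

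**Figure D2:**
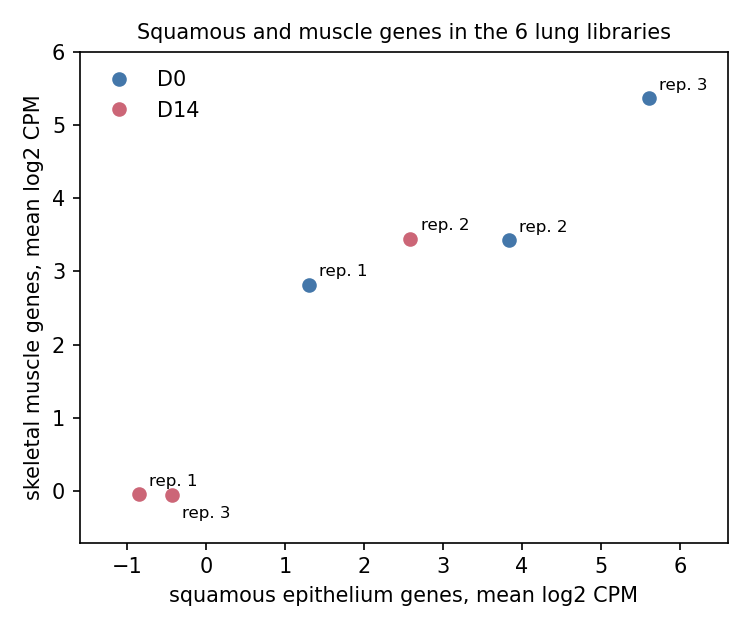
Mean log2 CPM of 15 squamous epithelium genes (horizontal axis) and of 15 skeletal muscle genes (vertical axis), 1 point per library, D0 in blue and D14 in red. D0 replicate 3 is highest on both axes, at 5.61 and 5.36, and D14 replicates 1 and 3 lie near −0.04 on the vertical axis.

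Genes for cytoplasmic ribosomal proteins were lower at D14 in 79 of 85 members, with a median log2 fold change of −0.40 (adjusted p = 4.78e-09, and adjusted p = 0.674 with an estimated correlation), and 0 fell adjusted over the list alone. Rpl4 stood at −0.13 (SE 0.17) and Rplp1 at −0.36 (SE 0.28). The list of nuclear-encoded respiratory chain genes was matched by symbol and includes some pseudogenes, such as Atp5pb-ps. It was lower in 70 of 86 members (median −0.30, adjusted p = 0.000530, and adjusted p = 0.849 with an estimated correlation). Atp5b stood at 0.21 (SE 0.19) and Atp5a1 at 0.05 (SE 0.16, negative without scaling factors). Without D0 replicate 3 the respiratory chain list had a median of −0.0289, with the test's direction upward (adjusted p = 0.767). Both lists hold short transcripts, with median lengths of 1049 and 977 bases against 3041.5 for all genes with a known length. With the genes outside the lists put into 4 equal classes of transcript length, the shortest class had a median log2 difference of −0.205 between D14 and D0, and the longest 0.200. Set against the mean of the 6 libraries, D0 replicate 3 had a median difference of 0.342 in the shortest class and −0.344 in the longest, and D14 replicate 3 of −0.167 and 0.167. Without D0 replicate 3 the median of the ribosomal protein list was −0.212, and without D14 replicate 1 it was −0.534, with 12 members past the threshold over the list alone.

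Mitochondrially encoded genes were higher in 12 of 13 members (median 0.49, adjusted p = 0.00186, and adjusted p = 0.674 with an estimated correlation), with mt-Co1 at 0.45 (SE 0.27) and mt-Cytb at 0.32 (SE 0.25), and the call was lost without D0 replicate 1 (adjusted p = 0.0631). Nuclear-retained noncoding RNAs were lower in 5 of 5 members (median −0.44, adjusted p = 0.0428, and adjusted p = 0.674 with an estimated correlation), with Malat1 at −0.24 (SE 0.21) and Neat1 at −0.44 (SE 0.20). That call was lost without D0 replicate 2, D0 replicate 3 or D14 replicate 1 (adjusted p = 0.135, 0.0792 and 0.0674) and without the low count filter (adjusted p = 0.198). Replication-dependent histone genes (median −0.16, adjusted p = 0.0613; H2bc4 −0.16, SE 0.24, and Hist1h2al −0.74, SE 0.31), hypoxia and glycolysis genes (median −0.0017, mean 0.01, adjusted p = 0.501; Aldoa −0.15, SE 0.27) and fatty acid and cholesterol synthesis genes (median 0.14, adjusted p = 0.0903; Scd1 1.03, SE 0.51, and Scd2 −0.12, SE 0.17) did not pass. Of the histone genes named, Hist1h2al is annotated as a processed pseudogene. Xist, the 1 member of the sex-linked list with enough counts, stood at 0.01 (SE 0.27), and that list was not tested as a group.

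**Figure D3:**
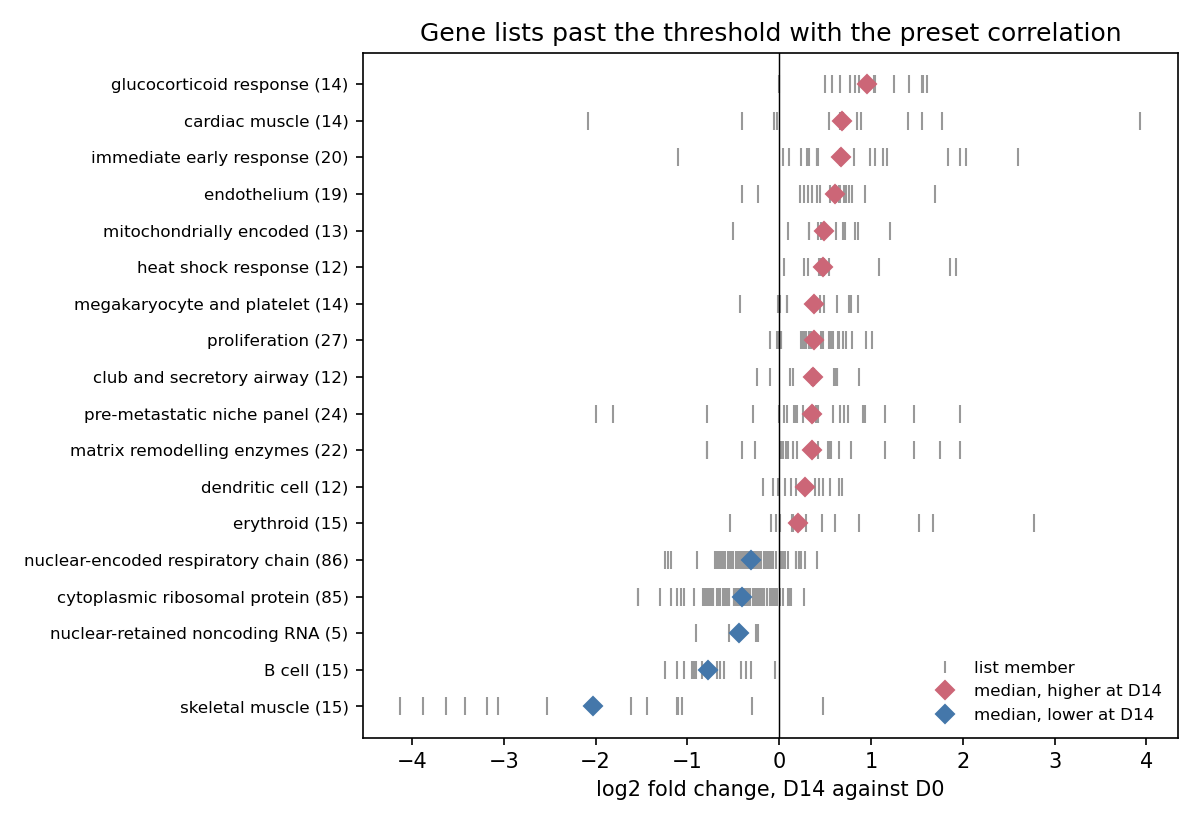
Log2 fold change of D14 against D0 for each member (grey ticks) and the median (diamonds, red for higher and blue for lower at D14) of the 18 lists that passed with the preset correlation; the number of measured members is in brackets. Medians run from −2.03 for skeletal muscle to 0.96 for the glucocorticoid response.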

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

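The summed-symbol alternative was chosen after the data were seen. The count of 6 genes, 3 higher and 3 lower, was the same with RLE factors, limma-voom, the stricter filter, no robust estimation and the added fold limit, and within 1.5 times with no scaling factors (4) and with repeated symbols summed (5). DESeq2 called 274 genes, 168 higher and 106 lower, and the fit with no low count filter called 26, of which 22 were higher; both include the 6. Leaving out 1 library gave 0 to 22 genes, 0 to 19 higher and 0 to 3 lower, with the sign of each of the 6 kept. All 6 passed without D0 replicate 3, Zfx and Mir1199 without D0 replicate 1, and none of them without another library. With no scaling factors Irs2 and Crk did not pass, each with an adjusted p of 0.0537. At an unadjusted p under 0.05 the fits without D14 replicates 1, 2 and 3 had 2083, 1234 and 1212 genes and those without D0 replicates 1, 2 and 3 had 3395, 1667 and 2102, against 2223 with all libraries. The cause was not tested. The count of 18 lists ranged from 17 to 22 except with an estimated correlation (0) and fry (0), both of which allow for the correlation between members. Correlation alone does not account for the loss with an estimated correlation. The dendritic cell and heat shock lists lost their calls at estimated correlations of −0.0708 and 0.0371. That test also rests on the few residual degrees of freedom of these libraries, so 0 calls do not show that members are correlated. With 3 libraries per day, and depths of 14878101 to 17385006 counts, simulated changes of a log2 fold change of 1 were recovered for 20.3% of genes.

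The shared replicate numbers were not taken as pairs: same-numbered libraries had deviations that correlated at 0.119, −0.0548 and −0.0972, and only D0 replicate 1 correlated best with its own number. With the replicate block, 0 genes passed, 0 higher and 0 lower, with 1483 at an unadjusted p under 0.05, and 19 lists did. Adjusted over the list alone, 1 heat shock gene and 0 erythroid genes passed with it, and the erythroid median was 0.594. The glucocorticoid count was 5, the niche panel count 3 and the endothelial count 1, and the type I interferon list passed (adjusted p = 0.0384). The skeletal muscle median was −3.0.

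Over the named genes 940 results under other settings kept direction and side of the threshold, 12 passed newly, 9 no longer passed and 23 changed sign. None of the sign changes was in a called gene, and the cause was not tested. The log2 fold changes that turned were, with no scaling factors, Timp2 −0.025, Tppp3 −0.061, Hba-a1 −0.020, Nrgn −0.073, Atp5a1 −0.012, Xist −0.077, S100a9 −0.029; with limma-voom, C3 0.059, Tppp3 −0.00094, Tef 0.26, S100a8 −0.056, S100a9 −0.055, Ccl2 −0.65, Cxcl1 0.23, Cxcl2 0.085; with the replicate block, C3 0.063, Tppp3 −0.0011, Tef 0.28, S100a8 −0.056, S100a9 −0.058, Ccl2 −0.16, Cxcl1 0.13; and with no low count filter, Ccl5 0.0015. Lists whose test turned had medians, with no scaling factors, of alternative macrophage activation −0.055, thymocyte −0.019, and with no low count filter, of classical monocyte −0.24, immune checkpoint 0.20, thymocyte 0.069.

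Leaving out 1 library turned the sign of genes that were not called, with log2 fold changes of Hp −0.060 to 0.30, Lcn2 −1.87 to 0.072, Gfi1 −0.85 to 0.16, Ccl6 −1.15 to 0.24, Apoe −0.21 to 0.87, Chil3 −1.62 to 0.015, Mrc1 −0.093 to 0.27, Ccl5 −0.27 to 0.17, Tcf7 −0.16 to 0.69, Gzma −0.58 to 0.065, Il2rb −0.063 to 0.63, Ighm −0.79 to 0.51. Further ranges were Igkc −0.84 to 0.58, Cd274 −0.26 to 0.081, Cd74 −0.20 to 0.19, H2-Aa −0.22 to 0.16, Bst2 −0.17 to 0.18, Gbp4 −0.11 to 0.67, Cxcl15 −0.29 to 0.10, C3 −0.32 to 0.19, Col3a1 −0.21 to 0.036, Timp2 −0.0019 to 0.14, Emp2 −0.17 to 0.13, Sftpa1 −0.33 to 0.14. Further ranges were Tppp3 −0.12 to 0.10, Hba-a1 −0.41 to 0.98, Hbb-bt −0.93 to 0.23, Nrgn −0.17 to 0.44, Cpa3 −0.84 to 0.075, Cma1 −0.60 to 0.26, Pcna −0.17 to 0.083, Myh7 −0.14 to 0.015, Car3 −1.69 to 1.71, Lpl −0.58 to 0.60, Tef −0.57 to 0.87, Jund −0.027 to 0.36. Further ranges were Aldoa −0.37 to 0.14, Scd2 −0.18 to 0.013, H2bc4 −0.29 to 0.17, Atp5a1 −0.013 to 0.12, Xist −0.24 to 0.17, S100a8 −0.43 to 0.39, S100a9 −0.36 to 0.36, Mmp9 −0.25 to 0.60, Saa3 −2.34 to 0.21, Ccl2 −0.84 to 0.74, Cxcl1 −0.77 to 1.06, Cxcl2 −0.71 to 0.64. List medians where the test turned without 1 library were neutrophil −0.019 to 0.44, granulocyte precursor (primary granule genes) −0.73 to 0.16, classical monocyte −0.23 to −0.010, alveolar macrophage −0.62 to 0.10, interstitial and monocyte-derived macrophage −0.54 to 0.26, alternative macrophage activation −0.61 to 0.27, T cell −0.25 to 0.31. Other medians were NK and cytotoxic lymphocyte −0.28 to 0.071, plasma cell −0.50 to 0.34, immune checkpoint −0.20 to 0.11, interferon gamma response −0.24 to 0.23, neutrophil and monocyte chemoattractant −0.60 to 0.10, acute phase and complement −0.49 to 0.19, fibroblast and myofibroblast −0.17 to 0.23. Other medians were alveolar type 2 −0.27 to 0.062, mast cell, basophil and eosinophil −0.75 to 0.26, adipose −1.41 to 1.21, thymocyte −0.42 to 0.62, hypoxia and glycolysis −0.066 to 0.14, nuclear-encoded respiratory chain −0.45 to −0.029.

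Among lists that passed, other medians moved by more than 1.5 times when 1 library was left out. They were 1.15 for cardiac muscle without D0 replicate 2, 0.155 and 0.594 for proliferation without D14 replicates 2 and 3, 0.765 and 0.185 for megakaryocyte and platelet genes without D0 replicates 1 and 3, 0.168 for club and secretory airway genes without D14 replicate 3, 0.322 for mitochondrially encoded genes without D14 replicate 3 and −0.229 for nuclear-retained noncoding RNAs without D0 replicate 2. The cause was not tested.

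Other lists gained a call with the preset correlation under some settings; the cause was not tested. With no scaling factors these were MHC class II (adjusted p = 0.0439) and classical macrophage activation (0.0439). With no low count filter they were MHC class II (0.0499), classical activation (0.0351), type I interferon (0.0284), ciliated airway (0.0486) and fatty acid and cholesterol synthesis (0.0311). With the stricter filter they were MHC class II (0.0462), classical activation (0.0279) and histone genes (0.0279). Leaving out D0 replicate 1 added MHC class II (0.0258), acute phase and complement (0.0266, downward) and ciliated airway (0.0136). Leaving out D0 replicate 2 added MHC class II (0.0488) and histone genes (0.0488). Leaving out D0 replicate 3 added alveolar type 1 (0.0366, downward), hypoxia and glycolysis (0.0494) and fatty acid synthesis (0.0383). Leaving out D14 replicate 1 added histone genes (0.03) and fatty acid synthesis (0.0121). Type I interferon passed without D14 replicate 2 (0.0109) or 3 (0.0134), ciliated airway without D14 replicate 2 (0.028) and fatty acid synthesis without D14 replicate 3 (0.0451). Removing the length trend added type I interferon (0.0103), ciliated airway (0.0102), classical activation (0.0419) and histone genes (0.0496). Other such calls stand in the report.

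DESeq2 gave, adjusted over the list alone, 7 matrix remodelling, 4 endothelial, 3 ribosomal protein and 1 skeletal muscle genes, no scaling factors gave 11 B cell genes and 1 endothelial gene, and limma-voom gave 4 B cell genes.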

Other observations

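The genes in this paragraph lie outside the rule and were chosen after their values were seen. Thbs1, thrombospondin 1, had 118 ± 34.8 CPM at D0 and 576 ± 278 CPM at D14, a log2 fold change of 2.29 (SE 0.39; adjusted p = 0.189, edgeR). Stc1, a secreted glycoprotein, had 7.64 ± 2.08 and 30.2 ± 4.33 CPM (1.98, SE 0.24; adjusted p = 0.0786). Insr, the insulin receptor, had 28.4 ± 15.1 and 101 ± 10.9 CPM (1.83, SE 0.42; adjusted p = 0.326) and Fosl2, an AP-1 subunit, 96.3 ± 25.0 and 276 ± 40.5 CPM (1.52, SE 0.23; adjusted p = 0.121). The D0 and D14 ranges of each did not overlap, as in 21.6% of the tested genes, where splits give 10% on average, in either direction. Without D0 replicate 3, Stc1, Insr, S1pr1, Lyve1 and Dusp8 were among the 22 genes called, with adjusted p of 0.0419, 0.0236, 0.0425, 0.0382 and 0.0223.

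The tests of single libraries, harvest time, handling and squamous genes and the counts over other splits were chosen after the results they bear on had been seen; the tests of transcript length were written down before, but the spread they are held to was chosen after. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 6 genes, and the highest of the others gave 1. For lists, 7 splits gave at least the real 18, and the highest of the others gave 24. With 10 splits no share under 0.05 can be reached.

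The first pattern is the shift of whole lists. Transcript length differed in its trend between libraries. Removing that trend left the respiratory chain list at a median log2 difference of −0.0452 (−0.228 before). Its call ended because the difference itself shrank (camera adjusted p = 0.345). The SE over libraries was 0.144 (0.241 before). Here and below, SEs over libraries and of the part removed are those of mean list scores, not of medians. Length may account for the list's lower level, but so may D0 replicate 3. Without that library the median log2 fold change was −0.0289. The length trend was also widest in that library, so these causes cannot be told apart. The ribosomal protein list stayed at −0.233 (−0.410 before; SE of the part removed 0.108; adjusted p = 8.31e-05), which exceeds 0.5 of its size by less than this SE, so length as its cause stays open. The endothelial list stayed at 0.671 (0.650 before, SE over libraries 0.283, camera adjusted p = 1.92e-06 with the preset correlation). The proliferation list stayed at 0.310 (0.336 before, SE over libraries 0.268, camera adjusted p = 0.000666 with the preset correlation). Their median transcript lengths, 3441 and 3421 bases, lie in the length class with a median log2 difference of 0.0173. The part removed was −0.0209 (SE 0.0254) and 0.0252 (SE 0.0261). Length thus accounts for little of either shift, and removing its trend could hardly have ended them. A change in RNA integrity, cell makeup or gene expression with the implant stays open for the lists that remain.

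The second pattern is the higher level of immediate early genes at D14. Removing the length trend left the median difference of their log2 CPM at 0.904 (0.789 before, SE of the part removed 0.0248). Their median log2 fold change in the gene test was 0.671 with all libraries and 0.725 without D0 replicate 3. Their median transcript length, 2521.5 bases, lay in the length class with a median log2 difference of −0.0936, against the direction of the shift. D0 replicate 3 had a mean log2 CPM of 6.71 for this list, between 6.05 and 6.79 in the other D0 libraries. These values argue against length or D0 replicate 3 as the whole cause, but neither removal could well have ended the shift. A low level in D0 replicate 1 stays open. Without that library the median log2 fold change was 0.418 and the mean score difference 0.608 (0.838 with all). Both exceed 0.5 of their size by less than the SE over libraries of the mean score difference, 0.252. Handling of the lungs between removal and lysis could raise these genes within minutes, and the heat shock list, at a median of 0.474, goes with it, but a difference in handling between the days cannot be told apart from the day itself. Time of day at harvest is open too. Ranges did not overlap in 4 of 18 clock genes (22.2%, against 21.6% of all tested genes and 10% on average over splits). Dbp differed by 3.54 log2 units within D0 and by −2.08 between the group means. A response to the implant remains an untested hypothesis.

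The third pattern is the lower level of skeletal muscle genes at D14, which went with a list of 19 squamous epithelium genes, 15 of them measured, 0 shared with the fixed lists and 3 at or above 1 CPM in every library. Over the 6 libraries the scores of both lists had a Pearson r of 0.962, but the squamous list was written after these libraries had been seen, so this does not test the relation. Tissue such as oesophagus, which in mice has a keratinised epithelium and striated muscle, taken along with some lungs is a candidate explanation that stays open: Krt4 had 10.3, 187 and 758 CPM at D0 and 0, 62.3 and 0 CPM at D14. How far the shift rests on D0 replicate 3 cannot be told apart: without it the list's median was −0.720, under 0.5 of its size, but the difference of its mean score went from −2.75 to −2.0, and without D14 replicate 2 the median was −5.32. A loss of muscle transcripts with the implant was not tested apart from this.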
